A study of Mus musculus with 31 samples.

How the data were processed

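RNA of hepatocyte and hepatic stellate cell preparations was sequenced from male and female C57BL/6J mice on chow or on the FPC diet. Per the submitters' protocol notes, liver cells were freed by enzyme digestion, hepatocytes were pelleted at low speed, and stellate cells were taken from the remaining cells on a Nycodenz density layer. Libraries were made with NuGEN Ovation kits, which amplify cDNA before library construction.

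The deposited table holds raw counts per gene symbol and library, made by the authors. Per the submitters' processing notes, reads were aligned with STAR to mm10 and counted with featureCounts. The versions of these tools, the strand setting and the annotation are not given in the sources used here. The table had 25239 symbols and 31 libraries, and every library was assigned to a group from its label. Of the symbols, 24374 matched the GENCODE M21 annotation of GRCm38, from which positions, GC content and transcript length were taken, and 865 did not.

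Each cell type was analysed by itself in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr, libraries were scaled by TMM, and one quasi-likelihood model with 4 groups (sex by diet) was fitted. Diet effects in each sex, sex differences on each diet and the interaction were contrasts of this model, tested on both sides with the Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. CPM values are scaled by TMM, and library levels of gene lists are means of log2(CPM + 1).

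Of 31 gene lists fixed beforehand, as were the comparisons, groups, naming rule and the first of the alternatives below, 29 were tested with camera of limma 3.58.1. The preset inter-gene correlation of 0.01 was used and then one estimated from the data, with adjustment over the lists of a comparison. A list needed at least 5 tested genes. The erythroid list was not tested, and the sex chromosome list served only to check labels. Counts of members adjusted over the list alone are given beside counts over all genes. The lipid droplet, acute phase, injury, retinoid, hepatocyte marker and lipid-associated macrophage lists each share 1 gene with another list, and the others share 0.

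Named genes followed a rule. For diet effects these were the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap between the groups (chance gives 2.86% of genes at 4 against 4) and whose mean was at least 5 CPM in the higher group. For sex differences the same rule gave 5 and 5, without the sex chromosome list. Where no gene was called, the 5 with the smallest p are given as not called. Up to 4 members with the smallest p were named for each list described. Gene models without a name were left out of all but the last part. Some genes that this rule would name are not reported here, in the text, in the plot of named genes or among libraries far from their group. Further genes whose CPM illustrates a list were taken from among these members.

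Where all libraries of a group had 0 counts, a bound against a floor of 3 counts over the group is given. Where a group had 1 to 3 counts, the ratio has an exact 95% counting interval. Both cover counting error only, since amplified reads are not independent molecules. Depth limits the shallowest library, hepatocyte male FPC 4, to 1.49 M counts (M, mega) outside ribosomal and Lars2 reads.

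Whether equal replicate numbers pair libraries was checked by correlating the deviations of libraries from their group means. Only the hepatocyte FPC groups of females and males paired, with correlations of 0.405, 0.577, 0.649 and 0.462, each the best match of its number, so blocked values of single genes are given for that comparison alone. Numbers in different preparations were not taken to mean the same mouse.

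The alternatives chosen before the data were examined were DESeq2 size factors in edgeR, DESeq2 1.42.0 with its own test, no filter, a fit of the compared groups alone, the replicate number as a block, a marker level as a covariate (Kupffer cells in hepatocyte libraries, hepatocytes in stellate cell libraries) and leaving out each library in turn. Chosen after the data were seen were GC and length offsets, leaving out Rn45s, Lars2 and Mir6236, the blocked fits of the FPC groups alone, and some further uses of planned settings.

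The pipeline was tested on simulated data in which 200 genes were changed. In the hepatocyte diet comparison of females it recovered 6% of 2-fold, 62.7% of 4-fold and 89.4% of 8-fold changes, and in that of males 0%, 53.7% and 78.8%. The interaction in hepatocytes recovered 1.5%, 20.9% and 59.1%. In stellate cell libraries the diet effect in females recovered 17.9%, 76.1% and 84.8%, that in males 11.9%, 70.1% and 93.9%, and the interaction 3%, 31.3% and 62.1%. A simulated GC trend called 1837 genes in hepatocytes and 2624 in stellate cell libraries, and 0 in each with the offsets. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.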

Results

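RNA sequencing counts were analysed for hepatocytes and hepatic stellate cells isolated from the livers of male and female C57BL/6J mice, a common inbred laboratory strain. The mice ate standard chow or the FPC diet, which is enriched in fructose, palmitate and cholesterol and is fed to mice to bring about steatohepatitis, for 16 weeks. Hepatic stellate cells are the vitamin A-storing pericytes of the sinusoids and can turn into matrix-producing myofibroblasts. Per the series design, the 4 mice of a group were independent animals. Each combination of cell type, sex and diet had 4 libraries, except stellate cells of chow-fed females with 3 (replicates 1, 2 and 4), which gave 31 libraries. The design asks how the diet changes each cell type in each sex, and whether females and males respond differently. Diet effects are given as FPC minus chow, sex differences as male minus female, and the interaction as the male diet effect minus the female one. Levels are mean ± SD of CPM, the counts scaled to a common library size, and log2 fold changes stand with their standard errors.

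Total counts per hepatocyte library, in mega (M), ran from 7.93 to 18.77 M in females on chow and 8.52 to 30.39 M in females on FPC. They ran from 3.44 to 14.21 M in males on chow and 6.33 to 27.26 M in males on FPC. Stellate cell libraries held 20.01 to 26.07, 9.44 to 40.26, 23.03 to 34.04 and 14.34 to 19.72 M in the same order. Hepatocyte male FPC library 4 gave 84.29% of its counts to the ribosomal precursor Rn45s and 10.25% to Lars2, which left 1.49 M counts for other genes. In the other libraries Rn45s took 0.1749% to 3.219%. The sex labels were checked on Xist, the RNA of the inactive X chromosome, with 187 to 39412 counts in female libraries and 0 to 59 in male ones. Genes of the Y chromosome had 0 to 27 counts in female libraries and 88 to 11875 in male ones. Libraries also differed in how their levels followed the GC content of transcripts, with a Spearman rho across genes of −0.697 to 0.776 per library. Genes are not independent replicates, so these correlations describe libraries. The median log2 fold change of all genes tested was 0.119 for the diet in female hepatocytes and 0.076 in male ones, and 0.164 and 0.186 with GC and length offsets.

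Marker lists fixed before the data were examined gave the make-up of the preparations, as the mean log2(CPM + 1) of a list with its SD over 4 libraries. Hepatocyte markers, which include albumin, stood at 10.28 ± 0.71 in female hepatocyte libraries on chow and 8.82 ± 0.68 on FPC, and at 11.19 ± 0.44 and 8.87 ± 1.22 in male ones. Markers of Kupffer cells, the resident macrophages of the liver, stood at 8.97 ± 0.36 and 7.44 ± 0.55 in females and at 8.08 ± 0.17 and 7.50 ± 0.45 in males. Markers of monocyte-derived and lipid-associated macrophages stood at 5.22 ± 0.39 and 6.12 ± 0.63 in females and at 4.83 ± 0.18 and 6.36 ± 0.35 in males. Endothelial markers stood at 9.05 ± 0.43 and 7.86 ± 0.84 in females and at 9.04 ± 0.28 and 8.18 ± 0.16 in males.

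**Figure D1:**
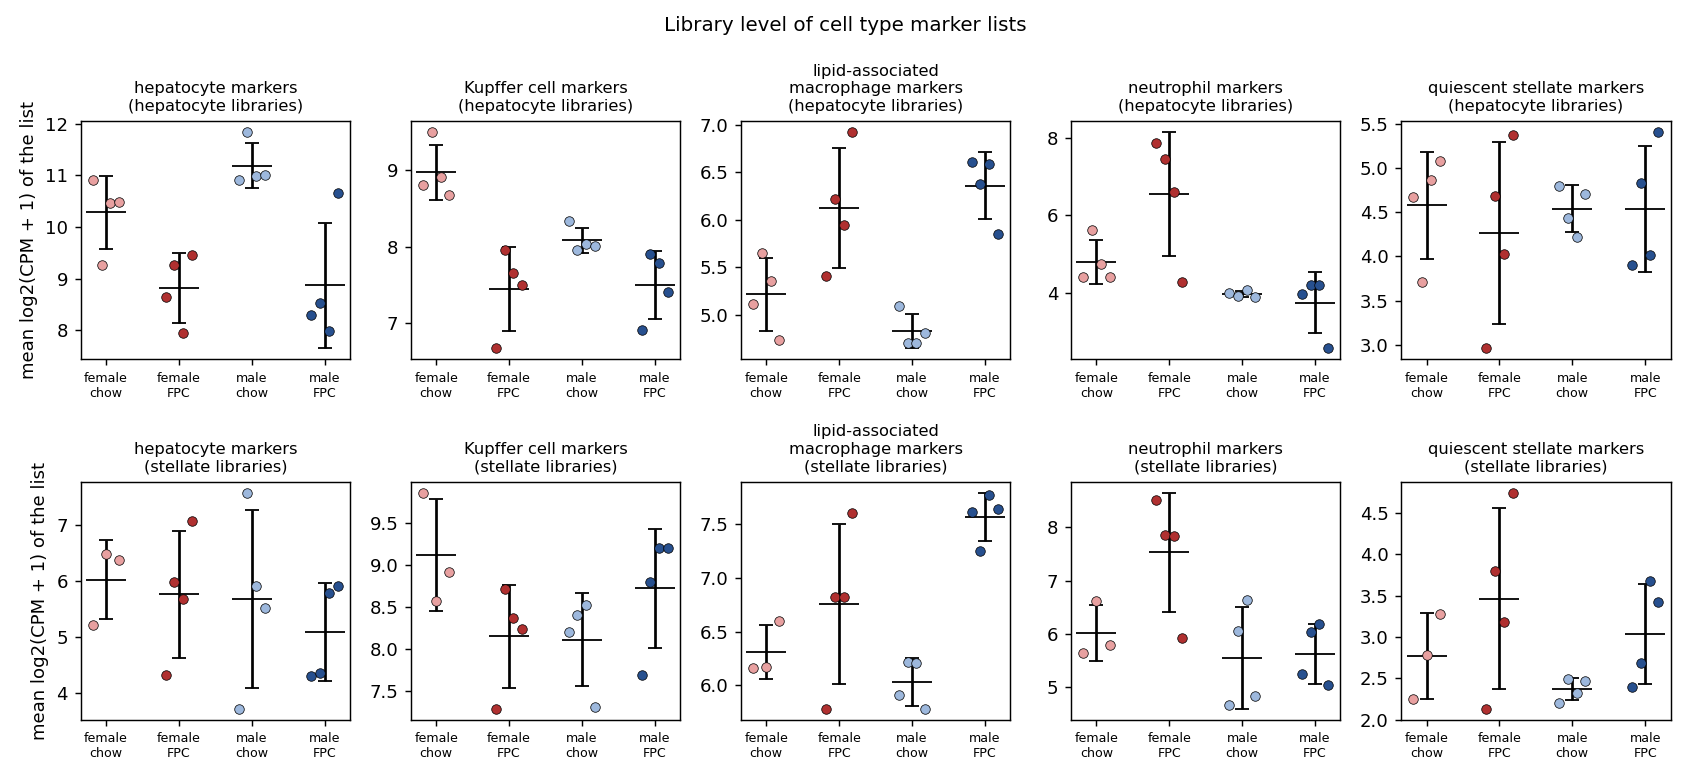
Library level of 5 cell type marker lists, as mean log2(CPM + 1) of the list on the y axis, in hepatocyte libraries (upper panels) and stellate cell libraries (lower panels) by sex and diet on the x axis. Points are libraries, dashes with bars are mean ± SD, y axes differ between panels, and the 2 cell types were normalised separately.

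In female hepatocyte libraries, the lists of female-type liver metabolism, cholesterol synthesis and resident macrophages passed camera, a test of gene lists, as lower on FPC than on chow. All 3 calls were lost with an estimated correlation between genes (adjusted p = 0.0664, 0.0715 and 0.0664), and values by estimated correlation below are adjusted p. The 5 genes called as higher were Cidec, H19, Saa1, Saa2 and Chil5, the last named after its values were seen, and the lipid droplet and acute phase lists did not pass (adjusted p = 0.874 and 0.263). The largest fall was that of A1bg, which encodes a secreted plasma protein, from 1580 ± 1490 to 38.2 ± 35.7 CPM (SD, n = 4; log2 fold change −5.38 ± 1.01, adjusted p = 0.0328). Cyp2b10, a xenobiotic-metabolising cytochrome P450 under control of the receptor CAR, fell from 44.5 ± 34.6 to 1.17 ± 0.879 CPM (−5.36 ± 0.84, adjusted p = 0.0165). Cidec, a protein that enlarges lipid droplets, rose from 0.737 ± 0.149 to 24.1 ± 28.2 CPM (4.98 ± 0.83, adjusted p = 0.0217). The imprinted fetal RNA H19 rose from 0.458 ± 0.246 to 7.39 ± 4.08 CPM (4.02 ± 0.70, adjusted p = 0.0226). The acute phase genes Saa1 and Saa2, near-identical copies whose reads cannot be told apart with certainty, rose by 3.18 ± 0.54 and 3.39 ± 0.57 (both adjusted p = 0.0217). Sult5a1 (−5.30), Dct (−4.59), Mup15 (−4.35), Mmd2 (−4.12) and Eci3 (−3.95) were the other leading falls, with adjusted p from 0.0165 to 0.0374, and Mup15 shares sequence with other major urinary protein genes. In all, 36 of 14430 genes passed the threshold, 5 higher and 31 lower on FPC. On the mouse build GRCm38 (mm10), A1bg lies on chromosome 15 from 60896859 to 60923012, Cyp2b10 on chromosome 7 from 25897620 to 25926624 and Cidec on chromosome 6 from 113424634 to 113435760.

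Of 19 measured female-biased liver genes, 12 fell in females adjusted over the list alone and 6 over all genes, with a median of −2.67 (camera adjusted p = 1.52e-14; 0.0664 by estimated correlation). Beside Cyp2b10 these included the transcription factor Cux2 (−2.67 ± 0.48, adjusted p = 0.025) and the steroid hydroxylase Cyp17a1 (−3.33 ± 0.61, adjusted p = 0.0275). Of 24 genes of cholesterol synthesis and uptake, 12 fell adjusted over the list alone and 1, the sterol reductase Tm7sf2 (73.6 ± 29.4 to 13.6 ± 7.06 CPM), over all genes, with a median of −1.11 (camera adjusted p = 1.52e-14; 0.0715 by estimated correlation). Beside this, hepatocyte markers had a median of −1.56 (6 of 15 lower over the list alone, among them Tat and Arg1; 0.282 by estimated correlation). Endothelial markers, Cdh5 among them, had one of −1.04 (6 of 14; 0.231 by estimated correlation; −1.61 without female FPC 2). Bile acid genes (median −1.38, with Cyp2c70, Baat and Akr1d1 lower over the list alone; 0.347), fructose and glucose genes (−0.94, with G6pc lower; 0.397) and oxidative stress genes (−0.70; 0.347) also passed camera as lower. The last number in each bracket is that by estimated correlation.

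Kupffer cell markers fell in females, 11 of 14 adjusted over the list alone, with a median of −1.44 (camera adjusted p = 4.77e-16; 0.0664 by estimated correlation). The scavenger receptor Cd163 fell from 97.2 ± 66.8 to 6.75 ± 4.22 CPM (−3.83 ± 0.56, adjusted p = 0.0165), and the resident macrophage genes Clec4f (−2.05 ± 0.46), Folr2 (−1.80 ± 0.38) and Timd4 (−1.58 ± 0.35) were lower over the list alone. Markers of lipid-associated macrophages rose (4 of 12 over the list alone, median 1.25; 0.231 by estimated correlation), among them Gpnmb (2.99 ± 0.64). Neutrophil markers rose (8 of 10 over the list alone, median 2.84; 0.233 by estimated correlation), with S100a8 at 65.9 ± 47.8 CPM on chow and 549 ± 581 CPM on FPC and Ly6g at 1.33 ± 0.918 and 11.4 ± 9.29 CPM. Erythroid markers, a list too short to test, stood at 4.11 ± 0.66 and 5.61 ± 2 beside them, with 8.26 in female FPC 2. Injury and fetal-type genes (median 0.87; H19 and Cd24a higher over the list alone), cholangiocyte (1.79), mesothelium (0.87), B and plasma cell (1.29) and activated stellate cell markers (0.61) passed camera as higher, with 0.231 to 0.578 by estimated correlation. Male-biased (−0.75), interferon (−0.54), fatty acid oxidation (−0.41), retinoid (−0.61) and fatty acid synthesis genes (−0.29) passed as lower, with 0.397 to 0.578 by estimated correlation. T and NK cell (0.76), cell cycle (0.29), portal fibroblast (0.86), collagen (0.44), acute phase (0.15), chemokine (−0.32), endoplasmic reticulum stress (−0.10) and quiescent stellate lists (−0.09) did not pass, nor did the lipid droplet list, whose median was −0.09, its mean 0.56 and its test upward. Without female FPC 4 the medians of the lipid-associated macrophage and injury lists were 0.36 and 0.23, still called, and those of the activated stellate (−0.01), cholangiocyte (1.13) and mesothelium lists (0.5) were not. The last 3 also lost their calls without female chow 2 (0.53, 1.55 and 0.61) or female FPC 2 (0.65, 1.46 and 0.51), and the activated list without female chow 4 (0.55). Without female FPC 1 the neutrophil median was 1.86, and the B and plasma cell (0.22), fatty acid oxidation (−0.35) and retinoid lists (−0.62) were not called. Nor were fatty acid oxidation without female chow 1 (−0.30), fatty acid synthesis (−0.20) and retinoid genes (−0.53) without female FPC 3, and interferon genes without female chow 2 (0.05). Larger falls stood without female FPC 4 for fatty acid synthesis (−0.63) and oxidation (−0.69), without female chow 2 for fatty acid synthesis (−0.51) and without female FPC 3 for interferon genes (−0.89).

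The female count was 0 without female chow 1, female chow 4 or female FPC 1, 7 without female chow 3, 15 without female FPC 3, 65 without female chow 2 and 167 without female FPC 2. It was 8 with the replicate number as a block, 0 in a fit of the female groups alone and 0 with the Kupffer marker level as a covariate (Kupffer median 0.34, interferon median 1.37), 58 with no filter, 89 with GC and length offsets and 639 by DESeq2. Across genes the effects had a rho of −0.182 with GC content and 0.205 with transcript length.

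**Figure D2:**
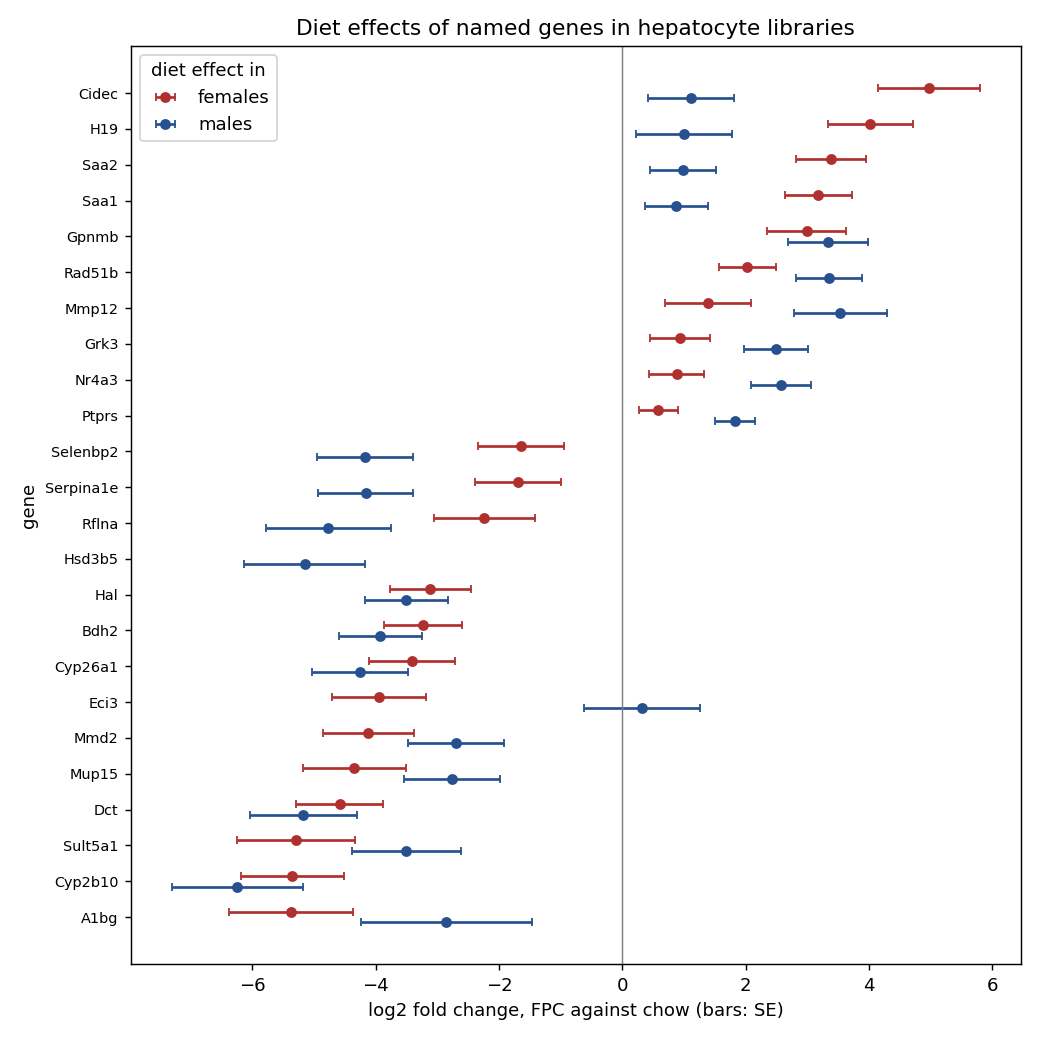
Log2 fold change of FPC against chow (x axis, bars are approximate standard errors from the F statistic) of the named genes (y axis) in female (red) and male (blue) hepatocyte libraries, n = 4 per group. The point of Hsd3b5 in females is not drawn because both group means are under 0.2 CPM; Cyp2b10 stands at −5.36 in females and −6.25 in males.

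In male hepatocyte libraries, the lists of cholesterol synthesis, male-type liver genes and hepatocyte markers passed camera as lower on FPC, and that of lipid-associated macrophages as higher. All 4 calls were lost with an estimated correlation (adjusted p = 0.0902, 0.136, 0.226 and 0.136). Cyp2b10 fell from 10.2 ± 6.23 to 0.383 ± 0.572 CPM (SD, n = 4; −6.25 ± 1.07, adjusted p = 0.0273). Hsd3b5, a male-type steroid dehydrogenase, fell from 157 ± 126 to 4.81 ± 4.17 CPM (−5.15 ± 0.99, adjusted p = 0.0445). Cyp26a1, which breaks down retinoic acid, fell from 11 ± 7.48 to 0.888 ± 1.08 CPM (−4.25 ± 0.78, adjusted p = 0.0343). Hal, the histidine-degrading ammonia lyase, fell from 421 ± 240 to 38.3 ± 39.1 CPM (−3.50 ± 0.67, adjusted p = 0.0349). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose from 14.8 ± 6.46 to 148 ± 33.4 CPM (3.33 ± 0.65, adjusted p = 0.0349). The macrophage elastase Mmp12 rose from 4.24 ± 2.22 to 49.4 ± 27.5 CPM (3.54 ± 0.76, adjusted p = 0.0499). Rad51b (3.35), the nuclear receptor Nr4a3 (2.58), the receptor kinase Grk3 (2.50) and the phosphatase Ptprs (1.84) were the other rises that met the naming rule, with adjusted p from 0.0185 to 0.0465. Further leading falls were Rflna (−4.77), Selenbp2 (−4.17), Serpina1e (−4.16) and Bdh2 (−3.92), with adjusted p from 0.0283 to 0.0488, and Selenbp2 and Serpina1e have near-identical copies that leave their counts uncertain. In all, 63 of 14430 genes passed the threshold, 11 higher and 52 lower on FPC. Gpnmb lies on chromosome 6 from 49036546 to 49070929, and Hsd3b5 on chromosome 3 from 98618634 to 98630252.

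Of 24 genes of cholesterol synthesis and uptake, 17 fell in males adjusted over the list alone and 6 over all genes, with a median of −1.57 (camera adjusted p = 3.56e-17; 0.0902 by estimated correlation). Nsdhl fell from 61.1 ± 15.1 to 12.3 ± 2.43 CPM (adjusted p = 0.00351), Msmo1 from 93.1 ± 17.2 to 20.9 ± 3.20 CPM (adjusted p = 0.0102). Tm7sf2 fell by 3.36 and the farnesyl diphosphate synthase Fdps fell by 2.61 on the log2 scale (both adjusted p = 0.0167). Of 19 male-biased liver genes, 14 fell over the list alone and 5 over all genes, with a median of −2.32 (camera adjusted p = 1.16e-13; 0.136 by estimated correlation). The fatty acid elongase Elovl3 fell from 237 ± 115 to 26.4 ± 15.2 CPM and the major urinary protein Mup3 from 1748 ± 651 to 244 ± 137 CPM, with adjusted p of 0.0445 and 0.0349. Hepatocyte markers fell beside these lists, 13 of 15 over the list alone, Arg1 and Serpina1a among them, with a median of −2 (0.226 by estimated correlation). Retinoid genes had a median of −0.90, with 6 of 15 lower over the list alone, Cyp26a1 and Rdh11 among them (0.367 by estimated correlation). Oxidative stress genes (−0.86; 6 of 20 lower over the list alone, Sod1 and Gstm2 among them), and fructose and glucose genes (−0.98; 3 of 16) passed camera as lower. So did endothelial markers (−1.01; 7 of 14, Dnase1l3 among them), acute phase genes (−1.11; Orm1 and Fgg) and bile acid genes (−1), all with 0.563 to 0.67 by estimated correlation. Without male FPC 4 the medians of the fructose and glucose, acute phase and bile acid lists were −1.80, −1.71 and −2.09.

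Markers of lipid-associated macrophages rose in males, 6 of 12 adjusted over the list alone, with a median of 1.25 (camera adjusted p = 1.19e-06; 0.136 by estimated correlation). Gpnmb and Mmp12 passed over all genes, and the monocyte receptors Cx3cr1 and Ccr2 over the list alone. Interferon response genes had a median of 0.86 (camera adjusted p = 0.00227; 0.67 by estimated correlation), with Oas2 higher over the list alone at 4.68 ± 2.13 CPM on chow and 25.0 ± 12.1 CPM on FPC. Kupffer cell markers had a median of −0.38 and passed as lower (0.67 by estimated correlation), with Cd163 lower over all genes (−2.80 ± 0.54, adjusted p = 0.0349) and Marco over the list alone. The list did not pass with GC and length offsets (median 0.13), nor without male chow 1 (−0.13), male FPC 1 (−0.10) or male FPC 4 (−0.25). T and NK cell (0.76), cell cycle (0.55) and activated stellate lists (0.38) passed as higher, with 0.67 to 0.757 by estimated correlation. All 3 lost their calls without male FPC 2 (0.77, 0.43 and 0.42). So did T and NK cell markers without male chow 4 (0.61), cell cycle genes without male chow 2 (0.49), male chow 4 (0.47) or male FPC 3 (0.53), and the activated list without male chow 3 (0.49) or male FPC 4 (0.24). The activated median was 0.61 without male FPC 1 and 0.66 without male FPC 3. The neutrophil list did not pass in males (median −0.03). The female-biased list did not pass either (median −0.14), and the fatty acid synthesis list had a median of 0.13, a mean of −0.01 and a downward test that did not pass.

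The male count was 0 without male FPC 1, 1 without male FPC 2 or male FPC 3, 2, 7, 9 and 37 without male chow 2, 3, 4 and 1, and 1438 without male FPC 4, the library rich in ribosomal RNA. It was 24 with the Kupffer marker level as a covariate, 39 with no filter, 40 with DESeq2 size factors, 131 in a fit of the male groups alone and 1298 by DESeq2. With GC and length offsets 74 passed, 42 of the 63 among them but not Mmp12, Rflna, Elovl3 and Arg1. The effects had a rho of −0.369 with GC content and 0.469 with transcript length.

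**Figure D3:**
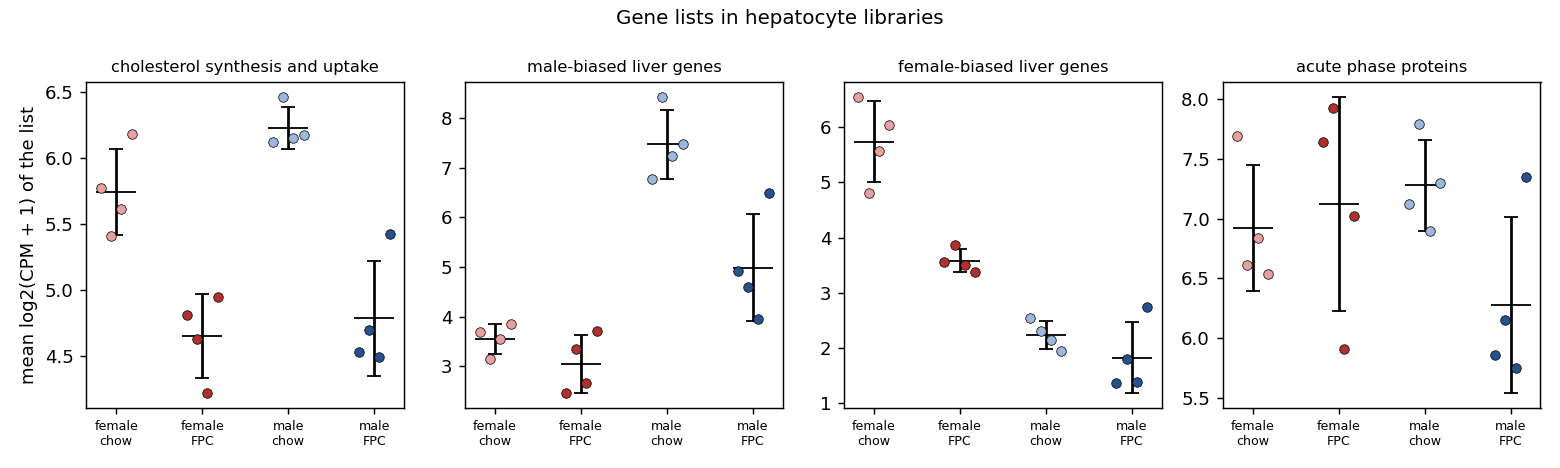
Mean log2(CPM + 1) of 4 gene lists (y axis) in hepatocyte libraries by sex and diet (x axis). Points are libraries and dashes with bars are mean ± SD, n = 4; the cholesterol list stood at 5.74 ± 0.33 and 4.65 ± 0.32 in females on chow and FPC and at 6.22 ± 0.16 and 4.78 ± 0.43 in males.

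The diet effects in hepatocyte libraries of females and males ran in the same direction for most genes. Across 14430 genes the Spearman correlation of the fold changes was 0.643 and Pearson's 0.608, 74.5% had the same sign, and of 89 genes called in either sex 84 had the same sign, with a Spearman correlation of 0.529. The falls in both sexes shared 10 genes, where independent lists of 31 and 52 would share 0.11, and the rises, 5 and 11, shared 0. The shared falls were Bhmt and Cth, enzymes of homocysteine and cysteine metabolism, the glutaminase Gls2, Cyp2b10, Tm7sf2, Bdh2, Dct, Gstt3, Ugt3a1 and the macrophage receptor Cd163. The groups compared in females and males share no library. The female and male FPC libraries of the same number deviated together, however (correlations of 0.405, 0.577, 0.649 and 0.462), so variation shared by these groups can raise the agreement.

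The test of whether the diet effect differed between the sexes in hepatocytes called 0 genes by edgeR, with 605 genes at an unadjusted p under 0.05 where chance gives 722, and 2 genes by DESeq2. The smallest p belonged to Serpina12, an adipokine of the serpin family, at 8.52 ± 3.17 and 28.4 ± 21.9 CPM in females and 140 ± 85.2 and 25.9 ± 8.08 CPM in males (interaction −4.19 ± 0.76, adjusted p = 0.559, not called). Cyp17a1 (3.96 ± 0.87), Elovl3 (−3.70 ± 0.90), C8b (−3.35 ± 0.82) and A2ml1 (−2.16 ± 0.54) followed, all at an adjusted p of 0.978. Of the gene lists, interferon genes had the smallest camera p, with a median interaction of 1.54 (20 of 20 above 0; camera adjusted p = 8.03e-12, 0.26 by estimated correlation). The median was 0.88 without female chow 2, whose interferon level was 6.89 against 4.96 to 5.03 in the other female chow libraries. Acute phase genes had −1.21 (0.283 by estimated correlation), with Saa1, Saa2, Orm1 and Orm2 past the list alone, and neutrophil markers −2.16 (0.26), with Mmp9 (−2.26 ± 0.63) and S100a8 (−3.42 ± 1.02) past it. Male-biased genes had −1.95 (0.26), with Elovl3 past the list alone, female-biased genes 1.73 (0.26), with Cyp17a1, Cux2 and Atp6v0d2 past it, and Kupffer markers 1.03 (0.26). The lipid droplet list had −0.31 (0.623), with Cidec past the list alone at −3.87 ± 1.03, and was no longer called with GC and length offsets (median −0.03) or without male FPC 1 (−0.07). It was −0.97 without male FPC 4. The male-biased median was −0.95 without female FPC 4, and without male FPC 4 the female-biased and acute phase medians were 0.80 and −1.86. With the Kupffer marker level as a covariate the medians of the Kupffer and lipid-associated macrophage lists were −0.17 and −0.12 and that of chemokines −0.32, from 1.03, 0.28 and 0.58, and those of interferon and cholesterol genes, 0.06 and −0.13, were not called. Without female FPC 4 the lipid-associated macrophage and chemokine medians were 0.96 and 0.93. Interaction effects had a rho of −0.326 with GC content and 0.422 with transcript length.

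On chow, male and female hepatocyte libraries differed in the sex-typed genes of the liver, which follow the pattern of growth hormone release. The female-specific sulfotransferases of the Sult2a family were nearly absent from males. Sult2a2 stood at 428 ± 166 CPM in females and 0.294 ± 0.352 CPM in males (SD, n = 4; −10.99 ± 0.76, adjusted p = 8.27e-07). Sult2a1 stood at 467 ± 186 and 0.31 ± 0.339 CPM (−10.94 ± 0.82, adjusted p = 1.34e-06). Sult2a3 and Sult2a5 had 0 counts in all male chow libraries and were at least 510-fold and at least 495-fold lower there, against a floor of 3 counts over the group. These near-identical genes lie together on chromosome 7 between 13623967 and 14123044, so their single values are uncertain. A1bg was lower in males (−10.55 ± 1.29, adjusted p = 0.000424). In the other direction the pheromone carrier Mup20 stood at 5.89 ± 2.83 CPM in females and 2160 ± 709 CPM in males (8.52 ± 1.25, adjusted p = 0.00201). The steroid transporter Slco1a1 stood at 0.476 ± 0.413 and 72.8 ± 37.7 CPM (7.41 ± 1.08, adjusted p = 0.00201). The fatty acid hydroxylase Cyp4a12b stood at 0.482 ± 0.817 and 94.3 ± 56.8 CPM (7.75 ± 1.60, adjusted p = 0.0393, not called with GC and length offsets). Hsd3b5, with 3 counts in the female group and 5367 in the male one, was higher in males by a ratio of 3380 (exact 95% interval 1160 to 16400, counting error only). The lipid droplet protein Cidea had 0 counts in females and was at least 159-fold higher in males. In all, 62 of 14430 genes passed, 43 higher and 19 lower in males.

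Of 19 male-biased genes, 17 were higher in males adjusted over the list alone and 10 over all genes, with a median of 3.72, and of 19 female-biased genes 16 and 8 were lower, with a median of −4.36. Both calls held with an estimated correlation (adjusted p = 0.00125 and 0.000146). Elovl3 stood at 1.78 ± 1.45 and 237 ± 115 CPM in females and males, and the oxysterol hydroxylase Cyp7b1 at 7.82 ± 2 and 151 ± 92.2 CPM. The lipid droplet list had a median of 0.43, also with Cidea at its bound, with Cidec higher over all genes at 0.737 ± 0.149 and 13.2 ± 2.03 CPM (adjusted p = 0.028; list 0.415 by estimated correlation). Interferon genes were lower in males, 12 of 20 adjusted over the list alone, with a median of −1.40 (0.35 by estimated correlation), among them Ifi27l2a at 217 ± 202 and 55.7 ± 5.03 CPM. The median was −0.50 without female chow 2, whose level is given above. Kupffer markers were lower beside them, 6 of 14 over the list alone, Folr2 and Adgre1 among them, with a median of −0.95 (0.161 by estimated correlation), and hepatocyte markers were higher (median 0.73; 0.415). Neutrophil markers were lower in males (4 of 10 over the list alone, 8 of 10 below 0, median −0.50, mean −1.32; 0.415). Cell cycle genes (−0.95), cholesterol genes (0.43) and T and NK cell markers (−0.59) also passed camera, with 0.379 to 0.415 by estimated correlation. So did the fructose and glucose (0.58), bile acid (0.74), mesothelium (0.87), retinoid (0.25), cholangiocyte (1.08), acute phase (0.37), chemokine (−0.51) and lipid-associated macrophage lists (−0.55), with 0.379 to 0.676. Without female chow 2 the medians of the cell cycle, cholesterol, lipid droplet, hepatocyte, mesothelium and retinoid lists were −0.41, 0.27, 0.24, 0.46, 0.54 and 0.16. Without male chow 2 those of the hepatocyte, lipid droplet, fructose and glucose, and bile acid lists were 0.37, 0.22, 0.27 and 0.49. The cholangiocyte call ended without female chow 3 (0.79), male chow 1 (0.75) or male chow 2 (0.58), and the chemokine call without female chow 3 (−0.32) or male chow 2 (−0.48). The lipid-associated macrophage call ended without female chow 2 (−0.15), female chow 3 (−0.45) or male chow 3 (−0.44), and its median was −0.35 without male chow 2. The retinoid median was 0.50 without female chow 3 and the acute phase one 0.68 without female chow 1. The acute phase call ended with GC and length offsets (0.36) and without female chow 2 (0.33), 3 (0.31) or 4 (0.14) or male chow 2 (0.20). The count was 37 without female chow 1, 41, 40 and 39 without male chow 2, 3 and 4, 13 with the Kupffer marker level as a covariate, 131 in a fit of the chow groups alone and 152 by DESeq2. That covariate did not overlap between the sexes, so cannot be told from sex. The effects had a rho of −0.07 with GC content and −0.159 with transcript length.

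On FPC the sex-typed liver genes still differed, and neutrophil markers, lower in males on chow too, were lower in male than in female hepatocyte libraries. Sult2a2 (ratio 1490, exact 95% interval 511 to 7240), Sult2a1 (1140, 391 to 5540) and Sult2a3 (639, 114 to 25300) were higher in females, with 3, 3 and 1 counts in the male group, and Sult2a5, at 0 counts there, was at least 228-fold lower in males. A1bg was lower in males (−8.03 ± 1.31, adjusted p = 0.0122), at 38.2 ± 35.7 and 0.156 ± 0.257 CPM in females and males. The cytochrome P450 Cyp3a41a (163 ± 122 and 4.01 ± 5.98 CPM, adjusted p = 0.0194) was lower in males too. Slco1a1 was higher in males at 0.267 ± 0.335 and 15.5 ± 19.5 CPM (5.89 ± 1.06, adjusted p = 0.0194). So were the major urinary protein genes Mup14 (5.59 ± 0.91, adjusted p = 0.0122), Mup12 (5.30 ± 0.94, adjusted p = 0.0181), Mup21 (5.12 ± 0.89) and Mup7 (5.06 ± 0.88, both adjusted p = 0.0178). These are near-identical copies whose single values are uncertain. In all, 48 of 14430 genes passed, 21 higher and 27 lower in males.

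Female-biased genes were lower in males on FPC (7 of 19 over the list alone, 4 over all genes, median −1.64, 0.0287 by estimated correlation). Male-biased genes were higher (12 of 19 and 4, median 2.30, 0.061 by estimated correlation), Mup3 and Elovl3 among them. Neutrophil markers were lower in males, 9 of 10 over the list alone and 5 over all genes, with a median of −3.70 (camera adjusted p = 9.94e-18; 0.0443 by estimated correlation). The granule proteins Ngp and Ltf stood at 649 ± 601 and 516 ± 489 CPM in females and at 8.86 ± 6.43 and 11.7 ± 4.75 CPM in males, with adjusted p of 0.0181 and 0.0194. Camp stood at 105 ± 91.6 and 2.63 ± 0.667 CPM (adjusted p = 0.0178), and Ly6g passed likewise (−4.39 ± 0.83, adjusted p = 0.0252). Erythroid markers, a list too short to test, stood at 5.61 ± 2 in females, and at 3.35 ± 0.52 in males, so more blood in the female preparations is not excluded. Acute phase genes were lower in males (6 of 20 over the list alone, median −0.71; 0.808 by estimated correlation), and Lcn2, which neutrophils also carry, passed over all genes (−3.76 ± 0.77, adjusted p = 0.0468). B and plasma cell markers were lower beside them (6 of 8, Fcmr and Cd79b among them, median −1.77; 0.24 by estimated correlation; −0.65 without female FPC 1). Without male FPC 4 the female-biased, male-biased and acute phase medians were −3.51, 1.45 and −1.40. Cell cycle (−0.81), bile acid (1.10) and collagen lists (0.20) also passed camera (each 0.943 by estimated correlation). The cell cycle call ended without female FPC 1 (−0.30) and the bile acid call without male FPC 4 (−0.15). The collagen call ended with GC and length offsets (0.25) and without female FPC 1 (−0.03), female FPC 3 (0.08), male FPC 2 (0.16) or male FPC 4 (−0.36), and stood at 0.38 (male FPC 3) to 0.79 (female FPC 4) without the others. In these FPC groups the libraries of the same number deviated together. A fit of these groups alone with the replicate number as a block called 42 (with 27 of the 48). Mup14 (5.87, adjusted p = 0.0911), Mup12 (5.67, 0.137), Mup7 (5.26, 0.106), Cyp3a41a (−6.52, 0.168) and Lcn2 (−3.15, 0.385) missed the threshold. Over all settings tried the adjusted p of these 5 genes ran from 3.88e-11 for Mup14 to 0.532 for Lcn2. With GC and length offsets that fit called 21 (14 of the 48) and lost Mup21, Mup3, Camp and Ltf too. Without the block, those offsets ended the calls of Slco1a1, Camp and Lcn2. The count was 11, 26, 98 and 74 without female FPC 1, 2, 3 and 4, and 15, 16 and 30 without male FPC 1, 2 and 3. It was 9 in a fit of the FPC groups alone and 179 by DESeq2, and the effects had a rho of −0.423 with GC content and 0.356 with transcript length.

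The stellate cell libraries held markers of many cell types, and markers of stellate cells stood lower in them than in the hepatocyte libraries. Quiescent stellate cell markers stood at 2.77 ± 0.52 in females on chow (SD, n = 3) and 3.46 ± 1.10 in females on FPC. They stood at 2.37 ± 0.14 in males on chow and 3.04 ± 0.60 in males on FPC (n = 4 each), and at 4.27 ± 1.03 to 4.58 ± 0.61 in the hepatocyte libraries. Kupffer markers stood at 9.12 ± 0.67, 8.15 ± 0.61, 8.11 ± 0.55 and 8.72 ± 0.71 in the stellate libraries in the same order, and B and plasma cell markers at 9.00 ± 0.33, 8.79 ± 0.72, 8.76 ± 0.24 and 8.18 ± 0.37. Hepatocyte markers stood at 6.02 ± 0.71, 5.76 ± 1.14, 5.68 ± 1.59 and 5.09 ± 0.88. Each cell type was normalised by itself, so a level set across both is a description. These levels argue against mainly stellate cell RNA, and the results below are of the whole preparation.

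In female stellate cell libraries no gene passed the threshold for the diet: edgeR called 0 of 15430 genes, with 1555 at an unadjusted p under 0.05 where chance gives 772, and DESeq2 called 267. The smallest p belonged to the chemokine receptor Ccr10, at 3.85 ± 0.749 CPM on chow (SD, n = 3) and 0.522 ± 0.228 on FPC (n = 4; −2.91 ± 0.47, adjusted p = 0.197, not called). The ribosomal proteins Rps23 (−0.99 ± 0.18) and Rps24 (−0.96 ± 0.18), the respiratory chain subunit Ndufa5 (−0.99 ± 0.18) and Rps23rg1 (−0.94 ± 0.17), a near-identical copy of Rps23, followed at the same adjusted p. Collagen and matrix genes passed camera as higher (7 of 28 over the list alone, median 1.76, camera adjusted p = 3.37e-07; 0.512 by estimated correlation). Among the 7, the fibrillar collagens Col1a2 and Col3a1 stood at 2.19 ± 0.916 and 4.33 ± 2.18 CPM on chow and at 16.2 ± 19.9 and 35.7 ± 45.1 CPM on FPC. Activated stellate markers (median 1.29; Lox and Ltbp2 past the list alone; 0.512 by estimated correlation) and quiescent ones (1.27; 0.565) also passed as higher. Without female FPC 4 the collagen, activated and quiescent lists had medians of 0.67, 0.54 and 0.41 and none of the 3 was called. Neutrophil markers rose (9 of 10 over the list alone, Ltf and Cxcr2 among them, median 1.95; 0.512 by estimated correlation) and Kupffer markers fell (median −0.70, Cd163 and Marco lower over the list alone; 0.512; −0.23 without female chow 1 and −0.45 without female FPC 1). T and NK cell markers passed as lower (median −0.65, with Gzma at 157 ± 18.1 and 40.8 ± 25.3 CPM; 0.512; −0.05 without female chow 2 and −0.39 without female FPC 1), as did endoplasmic reticulum stress genes (−0.29; Pdia6 and Asns lower over the list alone; 0.512), which were no longer called without female chow 1 (median −0.15) and stood at −0.50 without female chow 2 and −0.47 without female FPC 4. Lipid droplet genes had a median of 0.41 (0.565), with Cidec at 0.191 ± 0.171 and 5.95 ± 7.82 CPM and Plin4 at 0.258 ± 0.0876 and 5.82 ± 5.38 CPM past the list alone. They were no longer called without female chow 4 (0.45) or female FPC 4 (−0.01). Cell cycle (−0.72), acute phase (0.38), oxidative stress (−0.48), female-biased (−0.79), cholesterol (−0.23), endothelial (−0.51) and interferon lists (−0.29) passed too, with 0.512 to 0.683. Each of these 7 calls ended without some single library. These were female chow 1 (cell cycle 0.12, cholesterol −0.16, interferon −0.05) and female chow 4 (acute phase 0.48, oxidative stress −0.34, female-biased −0.72, endothelium 0.22). Others were female FPC 1 (oxidative stress −0.23, female-biased −0.52, endothelium −0.27, interferon −0.06) and female FPC 4 (cell cycle −0.58, acute phase 0.24, female-biased −0.86, interferon −0.35). GC and length offsets ended the interferon (−0.14) and oxidative stress calls (−0.18). Larger medians stood without female chow 1 (endothelium −0.86), female chow 4 (cholesterol −0.35), female FPC 1 (cell cycle −1.25, acute phase 0.63), female FPC 3 (interferon −0.49) and female FPC 4 (oxidative stress −0.86). The count of genes was 23 without female chow 4 and 963 without female FPC 4. The effects had a rho of −0.311 with GC content and 0.518 with transcript length.

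In male stellate cell libraries no gene passed the threshold for the diet: edgeR called 0 of 15430 genes, with 876 at an unadjusted p under 0.05, and DESeq2 called 66. Of 29 lists 17 passed camera, and of these the lipid-associated macrophage list alone kept its call with an estimated correlation. The genes with the smallest p were the fatty acid-binding protein Fabp5 (23.5 ± 3.25 CPM on chow and 109 ± 35.3 CPM on FPC, n = 4; 2.22 ± 0.37) and Mmp12 (13.1 ± 5.87 and 165 ± 93.3 CPM; 3.66 ± 0.64). Next came Gpnmb (16.7 ± 2.12 and 318 ± 138 CPM; 4.25 ± 0.76), the podosome adaptor Sh3pxd2b (1.90 ± 0.35) and the macrophage membrane protein Ms4a7 (2.20 ± 0.40), all at an adjusted p of 0.21 and not called. Markers of lipid-associated macrophages rose, 7 of 12 adjusted over the list alone, with a median of 0.90 (camera adjusted p = 4.51e-17), and the call held with an estimated correlation (adjusted p = 0.0165). Beside Mmp12 and Gpnmb these included Cd63 and the lipid receptor Trem2, the latter at 13 ± 1.98 and 75.6 ± 33.9 CPM. Interferon genes rose (5 of 20 over the list alone, median 0.86, camera adjusted p = 3.7e-17; 0.131 by estimated correlation), among them Oas1a (38.1 ± 6.16 and 113 ± 26.1 CPM), Ifi27l2a, Irf7 and Oasl1. Chemokine genes had a median of 0.75, with Ccl2 at 1.91 ± 0.52. They passed camera as higher, as did quiescent stellate (1.02) and activated stellate markers (0.91). Each of these lists had 0 members past the list alone and an adjusted p of 0.275 by estimated correlation. Collagens (median 0.65) passed likewise (0.45 by estimated correlation). Kupffer markers had a median of 0.98 (0.275 by estimated correlation), with Cd68 and C1qb higher and Cd163 lower (−2.19 ± 0.67) over the list alone. The lipid genes Cd36, Plin2 and Abhd5 were higher over the list alone (list median 0.26; 0.275 by estimated correlation). Male-biased genes (median −1.49; 0.275) and hepatocyte markers (−1.01; 0.556) were lower beside these, the latter not called without male chow 2 (−0.06) or male FPC 1 (−0.75), and the former at −0.53 without male chow 2. B and plasma cell (−0.61) and T and NK cell markers (−0.50) passed as lower, and oxidative stress (0.42), cell cycle (0.44), endoplasmic reticulum stress (0.29), injury (0.25) and fatty acid oxidation genes (0.23) as higher, with 0.275 to 0.599. The T and NK cell call ended without male chow 1 (−0.33), and that of fatty acid oxidation without male chow 1 or male FPC 4 (both 0.16), with 0.53 without male chow 2 and 0.13 without male FPC 3. The oxidative stress median was 0.27 without male FPC 3, and the lipid droplet median ran from 0.12 without male chow 1 to 0.45 without male chow 2, with 0.14 and 0.13 without male FPC 3 and 4. The count was 57 in a fit of the male groups alone and 2 with the hepatocyte marker level as a covariate, and the effects had a rho of 0.066 with GC content and −0.167 with transcript length.

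The diet-by-sex interaction in stellate cell libraries called 0 genes by edgeR, with 1341 at an unadjusted p under 0.05, and 56 by DESeq2. The smallest p belonged to Lypd11 (−3.86 ± 0.80), Begain (−3.40 ± 0.72), the signal peptidase subunit Spcs1 (1.10 ± 0.24), the proteasome assembly factor Pomp (1.20 ± 0.26) and the chemokine Ccl12 (3.90 ± 0.88), all at an adjusted p of 0.548. Interferon genes had a median interaction of 1.19 (20 of 20 above 0, 6 past the list alone, Isg15, Ifi27l2a, Oas1a and Irf7 among them, camera adjusted p = 8.61e-11; 0.389 by estimated correlation). Kupffer markers had 1.68 (6 of 14 past the list alone, Folr2 and Cd5l among them; 0.389 by estimated correlation), and endoplasmic reticulum stress genes 0.63 (Pdia6, Hspa5 and Asns past the list alone; 0.389). Oxidative stress genes had 0.66 (Txnrd1; 0.513), lipid-associated macrophage markers 0.87 (0.391) and neutrophil markers −2.09 (0.51; −1.30 without female FPC 1). Cell cycle (1.12), endothelial (0.61), male-biased (−1.74), acute phase (−1.15) and chemokine lists (0.43) passed camera too (each 0.773), the last not called with GC and length offsets (−0.05). Without female chow 1 the cell cycle median was 0.25, and without female chow 4 the endothelial one was −0.02 and not called, nor was it without female FPC 1 (0.40). Further calls that ended or moved without 1 library, male-biased, acute phase and chemokine ones among them, are given at the end. The count of genes was 1 without female chow 4, and the effects had a rho of 0.261 with GC content and −0.465 with transcript length.

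On chow, male and female stellate cell libraries differed in 8 genes of 15430, 4 of them the Y-linked Kdm5d, Uty, Eif2s3y and Ddx3y. Those lower in males were Sult2a2 (ratio of females over males 1690, exact 95% interval 466 to 13900) and Sult2a1 (26.5 ± 14.6 CPM, n = 3, and 0.057 ± 0.0732 CPM, n = 4; −8.81 ± 0.95, adjusted p = 0.000456). The others were A1bg (40.9 ± 24.1 and 0.118 ± 0.102 CPM; −8.29 ± 1.20, adjusted p = 0.0128) and the amino acid transporter Slc7a5 (97.2 ± 19.3 and 34.5 ± 6.66 CPM; −1.50 ± 0.22, adjusted p = 0.0138). Slc7a5 lies on chromosome 8 from 121881150 to 121907694. At an unadjusted p under 0.05 there were 4551 genes. Cell cycle genes were lower in males, 17 of 22 adjusted over the list alone, with a median of −1.68 (camera adjusted p = 3.57e-08; 0.948 by estimated correlation). The median was −0.81 without female chow 1, whose cell cycle level was 6.44 against 4.70 and 4.74 in the other female chow libraries. Endoplasmic reticulum stress genes were lower (8 of 18 over the list alone, Asns and Pdia6 among them, median −0.72; 0.948 by estimated correlation). Kupffer markers (median −0.98, 14 of 14 below 0; camera adjusted p = 0.00124; 0.948) and oxidative stress genes (−0.78, 6 of 20 over the list alone; camera adjusted p = 0.00274; 0.948) were lower beside these. The Kupffer call ended with GC and length offsets (−0.60, adjusted p = 0.0678) and the median was −0.61 without female chow 1, and the oxidative stress call ended without female chow 4 (−0.63). Male-biased liver genes were higher (12 of 19, median 2.92; 0.948), Elovl3 and Mup20 among them, and female-biased ones lower (8 of 18, median −2.02; 0.338), with medians of 1.25 and −3.70 without male chow 2. In these groups the mean rho of library levels with GC content was 0.33 ± 0.32 in females and −0.48 ± 0.09 in males, and the effects had a rho of −0.556 with GC content and 0.557 with transcript length. The count was 3019 without female chow 4, 2962 in a fit of the chow groups alone, 16 with GC and length offsets, 47 with the hepatocyte marker level as a covariate and 2452 by DESeq2.

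On FPC the stellate cell libraries of males and females differed in 9 genes, the 4 Y-linked genes and Ccdc117 higher in males, and Xist, Sult2a2, Sult2a1 and Prss34 lower. Ccdc117 stood at 45.8 ± 2.66 CPM in females and 94 ± 14.6 CPM in males (SD, n = 4; 1.04 ± 0.16, adjusted p = 0.0296). Prss34, a protease of basophils and mast cells, stood at 13.9 ± 8.63 and 1.41 ± 0.393 CPM (−3.31 ± 0.51, adjusted p = 0.0215). They lie on chromosome 11 from 5528887 to 5542187 and on chromosome 17 from 25298394 to 25300165. Sult2a2 (ratio of females over males 905, exact 95% interval 162 to 35800) and Sult2a1 (648, 116 to 25600) had 1 count each in the male group, as had A1bg (165, 29.2 to 6560), which was not called (adjusted p = 0.104). Neutrophil markers were lower in males, 6 of 10 adjusted over the list alone, Camp, Ngp and Ltf among them, with a median of −1.94 (camera adjusted p = 6.36e-09; 0.368 by estimated correlation), and erythroid markers stood at 5.35 ± 0.21 in females and 4.35 ± 0.61 in males. Acute phase genes were lower (median −1.13, with Lcn2 past the list alone; 0.515 by estimated correlation) and interferon genes higher (median 0.55, 20 of 20 above 0; 0.515; 0.33 without female FPC 1). Hepatocyte markers were lower beside these (median −1.06, 13 of 15 below 0, camera adjusted p = 0.00911; 0.739), and Kupffer (0.61, camera adjusted p = 0.00147; 0.671) and lipid-associated macrophage markers (0.41, camera adjusted p = 0.00583; 0.517) were higher. The hepatocyte call ended without female FPC 2 (−1.12), female FPC 4 (−0.09), male FPC 1 or male FPC 2 (both −0.81). The Kupffer call ended without female FPC 1 (0.36), and that of lipid-associated macrophages without female FPC 1 (0.11) or 2 (0.24), while its median was 0.97 without female FPC 4. The T cell chemokines Cxcl10 (14.0 ± 5.28 and 50.9 ± 17.1 CPM) and Cxcl9 (36.1 ± 15.8 and 103 ± 34.8 CPM) were higher in males over the list alone (list median 0.37; 0.602 by estimated correlation; not called without female FPC 1, median 0.16; 0.67 without female FPC 2 and 0.70 without female FPC 4). B and plasma cell markers were lower (5 of 8, Fcmr and Cd79a among them, median −1.11; 0.515; −0.52 without female FPC 1). Quiescent and activated stellate markers passed camera as lower (medians −1.10, with Ngfr past the list alone, and −0.77; both 0.739) and had medians of −0.10 and 0.17 without female FPC 4. Both calls also ended without female FPC 2 (−1.15 and −0.83) or male FPC 1 (−0.90 and −0.69), and the activated one without male FPC 2 (−0.56) and with GC and length offsets (−0.59, adjusted p = 0.108). With these offsets Ccdc117 (0.85, adjusted p = 0.0904) and Prss34 (−3.11, adjusted p = 0.0642) missed the threshold too. Female-biased (−2.73), male-biased (0.57), lipid droplet (−0.29), cell cycle (−0.48; 0.11 without female FPC 1), endothelial (0.32) and cholangiocyte lists (0.20) also passed camera, with 0.132 to 0.739. The cholangiocyte median was 2.04 without female FPC 4 and still called, and not called without any other but male FPC 3, at −0.14 (female FPC 1) to 0.19 (male FPC 1). The endothelial one was 0.63 without female FPC 4 and 0.52 without male FPC 2, and not called without any other, at 0.08 (female FPC 1) to 0.36 (female FPC 2). The lipid droplet one was −0.45 and −0.49 without male FPC 3 and 4, and not called without female FPC 2 or 4 or male FPC 1 or 2 (−0.39 to −0.07) or with GC and length offsets (−0.33). With the hepatocyte marker level as a covariate the lipid droplet, quiescent and activated calls ended (−0.16, −0.22 and −0.33) and, by construction, the hepatocyte one (−0.05). In a fit of the FPC groups alone the female-biased call ended (−0.25). The male-biased one ran from 0.26 without female FPC 1 to 1.04 without female FPC 4, and the cell cycle call ended without male FPC 1 (−0.41). The count was 40 without female FPC 4, 15 with the hepatocyte marker level as a covariate and 145 by DESeq2, and the effects had a rho of −0.601 with GC content and 0.274 with transcript length.

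The diet effects in stellate cell libraries of females and males had a Spearman correlation across genes of −0.112 (Pearson 0.032), with 43.2% of genes of the same sign. Between hepatocyte and stellate libraries of females, over 14211 genes, it was 0.386 (Pearson 0.411), and 33 of 33 genes called in hepatocytes had the same sign in stellate cell libraries. In males it was −0.073 (Pearson 0.114), and 52 of 60 called genes had the same sign. Deviations of hepatocyte and stellate libraries of the same group and number had correlations of −0.578 to 0.879, with 0.835 and 0.879 for female FPC 1 and 3. Such shared variation and hepatocyte RNA in the stellate cell libraries can raise this agreement.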

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

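Of the tests below, only that of the hepatocyte share by endothelial markers, those with GC and length offsets, and the splits by genes outside the X and Y chromosomes or parting every pair were chosen after the results were seen.

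The fall of the cholesterol synthesis list on FPC was weighed against make-up and quality of the preparations. The endothelial list fell too (medians −1.04 in females, −1.01 in males). Endothelial and hepatocyte shares can fall together, so this cannot test a lower hepatocyte share. With GC and length offsets the cholesterol list kept a median of −1.29 in males and −1.02 in females, and without the male library rich in ribosomal RNA it had −1.65, which argues against these as the whole cause. A lower hepatocyte share or a change in cell types that rose stays open. Hepatocyte markers fell more (−1.56 in females, −2 in males). A response of hepatocytes to dietary cholesterol may be the cause and was not tested.

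The 4551 genes at an unadjusted p under 0.05 between male and female stellate cell libraries on chow were weighed against GC and length trends and hepatocyte RNA. With GC and length offsets there were 3785, and with the hepatocyte marker level as a covariate 4390, so neither could be the whole cause. The share of other cell types and a biological sex difference stay open and were not tested.

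Sult2a1, Sult2a2 and A1bg, called between the sexes in stellate cell libraries, may be hepatocyte RNA carried into these libraries. In females on chow the median log2 ratio of stellate to hepatocyte CPM of these genes was −4.14, within the −5.13 to −3.04 of the hepatocyte marker genes (median −4.36). On FPC it was −2.46, within −4.59 to −1.78 (median −2.93). Both are what carried-over hepatocyte RNA would give.

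Other splits of the same libraries into groups of the same sizes tested each count of called genes. Chance can be excluded for the diet effect in male hepatocytes (63 genes, highest other split 0, 1 of 35 splits as large with the real one). Counts of sex differences hold Y-linked genes and Xist, whose calls follow from the sex labels, so genes outside the X and Y chromosomes were also adjusted and counted by themselves. So counted, no other split was as large for the sex difference in hepatocytes on chow (55, highest other 1, 1 of 35, and in all 62, highest other 1). On FPC, 5 of the 9 genes called in stellate cell libraries (highest other 1, 1 of 35) were such sex chromosome genes, so the total does not bear on chance. Outside the X and Y chromosomes 2 genes were called there, the near-identical Sult2a1 and Sult2a2 (highest other 1, 1 of 35), while Ccdc117 and Prss34 missed the threshold. The 2 amount to 1 signal, so the smallest p of each split was compared too. It was 1.17e-07 in the real one and 6.08e-07 in the lowest other (1 of 35), again the lowest share. Chance cannot be excluded for the diet effect in female hepatocytes (36, highest other 801, 2 of 35) or for the sex difference in stellate cell libraries on chow (8, highest other 29, 3 of 35; outside the X and Y chromosomes 4, highest other 28, 3 of 35; smallest p 3.56e-08, lowest other 1.10e-07).

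The sex difference in hepatocytes on FPC (48, highest other 2253, 3 of 35; outside the X and Y chromosomes 39, highest other 2198, 3 of 35) was set against splits that ignore the pairing of its libraries by number. The split with 2253 genes left every pair together, and that with 92 parted 2 of the 4. Among the 8 splits that part all 4 pairs, the real one called 39 genes outside the X and Y chromosomes and the highest other 2. With the replicate number as a block in the FPC groups alone these were 37 and 0. The 8 splits are too few for a share under 0.05. Among such genes the smallest p was 2.75e-10 (4e-07 in the lowest other of 35), for 1 gene alone.

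A count of 0 is matched by every split whatever the data, so the splits do not bear on chance in the comparisons that called 0 genes, 35 of 35 for the diet effects in stellate cell libraries (highest other 5118 in females and 0 in males) and 100 of 100 for the interactions (highest other 4121 in hepatocytes and 0 in stellate cell libraries). The splits with 801, 2253, 4121 and 5118 genes point to a structure of the libraries other than the groups, and that of 5118 exchanged the groups of female chow 4 and female FPC 4.

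A library lay far from the other 3 of its group in 26 of 254 sets. Chance gives about 13, though this may not hold near 0 CPM. Male FPC hepatocyte library 4 gave 84.29% of its counts to Rn45s and had the lowest T and NK cell (3.78) and neutrophil (2.57) marker levels of its group. Its Cyp2b10 and Rflna were highest at 1.232 CPM, on few counts. In hepatocyte libraries the B and plasma cell level was 7.01 in female chow 2 and the hepatocyte level 11.84 in male chow 2. In stellate cell libraries female FPC 1 had 40.26 M counts (M, mega), male chow 1 an endothelial level of 8.34 and male chow 4 an erythroid level of 6.79. Among hepatocyte libraries of females on chow, A1bg was at 3814 CPM in library 1, Mup15 at 198.4 and A2ml1 at 2.9 CPM in library 2, and Cyp4a12b at 1.706 CPM in library 4. On FPC, Sult5a1 was at 0.7576 CPM in female library 4, and Eci3 at 2.048, Sult2a2 at 154.9 and Sult2a1 at 158 CPM in female library 2. In males, Mup20 was at 3211 CPM in chow 2, Sult2a2 and Sult2a1 at 0.8186 CPM each in chow 1, and Sult2a3 at 0.1081 and A1bg at 0.5403 CPM in FPC 2. In male stellate cell libraries on FPC, Fabp5 was at 56.52 CPM in library 2, and Sult2a2 and Sult2a1 at 0.07313 CPM each in library 3.

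The interaction test gave 24 of 58 lists whose diet effect differed between the sexes with the preset correlation, and 0 with an estimated one. The median differences of the male from the female effect in hepatocyte libraries were −0.49 for cholesterol synthesis, −0.31 for lipid droplets, −1.95 for male-biased genes, 1.73 for female-biased genes, −1.21 for acute phase proteins, 0.58 for chemokines and 1.54 for interferon response. For marker lists there they were −0.56 for hepatocytes, 1.03 for Kupffer cells, 0.28 for lipid-associated macrophages, −1.26 for B and plasma cells, −2.16 for neutrophils and −1.16 for mesothelium. Those in stellate cell libraries were −1.74 for male-biased genes, −1.15 for acute phase proteins, 0.63 for endoplasmic reticulum stress, 0.66 for oxidative stress, 0.43 for chemokines, 1.19 for interferon response and 1.12 for cell cycle. For marker lists there they were 1.68 for Kupffer cells, 0.87 for lipid-associated macrophages, 0.61 for endothelium and −2.09 for neutrophils. Calls that ended without 1 library in hepatocyte libraries were those of lipid droplets without male FPC 1 (−0.07), hepatocyte markers without female chow 2 (−0.24) or male FPC 3 (−0.23), B and plasma cells without female FPC 1 (−0.02) or male FPC 4 (−1.02), and mesothelium without female FPC 4 (−0.71). That of lipid-associated macrophages ended without female chow 2 (0.26) or 3 (0.03), female FPC 1 or 3 (both 0.10), male chow 3 (0.12) or 4 (0.22), or male FPC 1 (0.34) or 2 (0.39). Those in stellate cell libraries were those of male-biased genes without female FPC 4 (−1) or male chow 2 (−0.73), chemokines without female FPC 1 (0.21) or male chow 4 (0.33), and endothelium without female chow 4 (−0.02) or female FPC 1 (0.40). That of acute phase proteins ended without female chow 4 (−1.18), female FPC 2 (−1.10) or 4 (−1.03), male chow 2 (−0.25), or male FPC 1 (−1.12) or 2 (−1). The interferon difference in hepatocyte libraries was 0.88 without female chow 2, and the cell cycle one in stellate cell libraries 0.25 without female chow 1 and 1.74 without female FPC 1. Other calls stood while their medians moved. Without male FPC 4, hepatocyte libraries gave −1.72 for hepatocyte markers, −0.77 for cholesterol synthesis, −0.97 for lipid droplets, −1.86 for acute phase proteins and 0.80 for female-biased genes. Without female FPC 4 they gave −0.95 for male-biased genes, 0.93 for chemokines and 0.96 for lipid-associated macrophages, and stellate cell libraries 1.43 for oxidative stress, 0.79 for chemokines and 0.93 for endothelium. The weakest medians still called were −0.23 for cholesterol synthesis (without female FPC 2), −0.13 for lipid droplets (male FPC 3), −0.25 for hepatocyte markers (female FPC 4), 0.32 for chemokines (female FPC 1) and, in stellate cell libraries, −1.30 for neutrophils (female FPC 1).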

How the results depend on the processing

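The tests with GC and length offsets, without ribosomal genes and with blocks in the FPC groups alone were chosen after the data were seen. In the order diet effect in females, diet effect in males, interaction, sex difference on chow and on FPC, DESeq2 called 639, 1298, 2, 152 and 179 genes in hepatocytes and 267, 66, 56, 2452 and 145 in stellate cell libraries. The cause was not tested.

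In hepatocytes the diet effect in females gave 58 genes with no filter, 0 in a fit of the female groups alone, 0 with the Kupffer level as a covariate and 89 with GC and length offsets. That in males gave 40 with DESeq2 size factors, 39 with no filter, 24 with the covariate and 131 in a fit of the male groups alone. The sex difference on chow gave 13 with the covariate and 131 in a fit of the chow groups alone, and that on FPC 9 in a fit of the FPC groups alone. In stellate cell libraries the diet effect in males gave 2 genes with the hepatocyte level as a covariate and 57 in a fit of the male groups alone. The sex difference on chow gave 47 with the covariate, 2962 in a fit of the chow groups alone and 16 with GC and length offsets, and that on FPC gave 15 with the covariate. Agreement of diet effects between the sexes in hepatocytes was 0.529 over genes called in either sex, from 0.643. The cause was not tested.

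With the replicate number as a block in the 4-group fit, the diet effect in female hepatocytes gave 8 genes, and the other 9 comparisons stayed within 1.5 times their counts. In the FPC groups of hepatocytes alone the block gave 42 genes, and 21 with GC and length offsets. The block left 137 list calls in place and ended 2.

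Leaving out each library in turn gave 0 to 167 genes for the diet effect in female hepatocytes and 0 to 1438 in male ones. It gave 0 to 0 for the interaction, 37 to 46 for the sex difference on chow and 11 to 98 for that on FPC. The ranges in stellate cell libraries were 0 to 963, 0 to 0, 0 to 1, 6 to 3019 and 6 to 40. Of list calls over these settings 1139 kept their side of the threshold and their direction, 125 were lost and 8 turned direction.

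Directions turned with the marker covariate, which was built from genes of the Kupffer list itself in hepatocytes. For the diet effect in female hepatocytes Folr2 had 0.13, Timd4 0.02, Clec4f 0.21, Irf7 1.36, the interferon list 1.37 and the Kupffer list 0.34, and in males the Kupffer list had 0.27. For the interaction in hepatocytes chemokines had −0.32, Kupffer markers −0.17 and lipid-associated macrophage markers −0.12. For the sex difference on chow Folr2 had 0.01, chemokines 0.29, interferon genes 0.03, Kupffer markers 0.04, lipid-associated macrophage markers 0.12 and T and NK cell markers 0.03. Hepatocyte markers in stellate cell libraries had 0.06 for the diet effect in males.

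Leaving out a library turned the direction of some list tests. The interferon list in female hepatocytes ran from −0.89 to 0.05 (without female chow 2). Collagens in the sex difference of hepatocytes on FPC ran from −0.36 (without male FPC 4) to 0.79, with −0.03 without female FPC 1. For the diet effect in female stellate cell libraries, cell cycle genes ran from −1.25 to 0.12 (without female chow 1) and endothelium from −0.86 to 0.22 (without female chow 4). For the sex difference there on FPC, cell cycle genes ran from −0.68 to 0.11 (without female FPC 1). Activated stellate markers ran from −1.10 to 0.17 and quiescent ones from −1.41 to −0.1, both highest without female FPC 4, where the quiescent test turned but its median did not. The cause was not tested.

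With an estimated correlation 134 list calls were lost and 5 held: both sex-biased lists in hepatocytes on chow, female-biased genes and neutrophil markers there on FPC, and lipid-associated macrophage markers for the diet in male stellate cell libraries. GC and length offsets kept 129 list calls and ended 10, DESeq2 size factors kept 138 and ended 1. Of named genes, 203 kept their call or lack of one with GC and length offsets, 5 gained a call and 10 lost it.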

Other observations

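The genes below were chosen after their values were seen, and no tests were run on them. In stellate cell libraries the stellate cell genes Lrat and Des stood at 8.5 ± 10.6 and 5.24 ± 2.33 CPM in females on chow (SD, n = 3) and at 7.02 ± 2.2 and 2.57 ± 1.37 CPM in males on chow (n = 4). In hepatocyte libraries they stood at 27 ± 25 and 52.6 ± 29.1 CPM in females and at 21.5 ± 9.37 and 55.3 ± 20.7 CPM in males on chow. The myeloid gene Lyz2 stood at 4931 ± 1280 and 3600 ± 1306 CPM in stellate cell libraries of females and males on chow, and the leukocyte gene Ptprc at 564 ± 279 and 1597 ± 83 CPM. Each cell type was normalised by itself.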
